A study of Mus musculus with 79 samples.

How the data were processed

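RNA was measured by sequencing in 79 libraries from lumbar dorsal root ganglia of BAC-TRAP BR145-GFP mice, naive or at 1 h, 12 h, 24 h, 48 h, 72 h and 7 d after bilateral sciatic nerve crush. Input is total RNA and IP is RNA pulled down with a chicken antibody to GFP on magnetic beads, per the labels' protocols. Libraries were made with SMART-Seq v4 and Nextera XT and sequenced as 75 bp paired-end reads in 1 lane, per the labels' protocols. Base calls were made with bcl2fastq 2.17, and STAR, HTSeq and the builds GRCm38 and mm10 are named without versions, per the submitters' processing notes. Strandedness, the treatment of multi-mapping reads and all alignment and counting settings are not given in the sources used here. The authors deposited a table of read counts per RefSeq gene symbol and a table of read counts per short genomic interval with a repeat element name. How the authors chose the intervals is not given in the sources used here.

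The gene table holds 24060 symbols, of which 27 that a spreadsheet had turned into dates were left out. They held 0.0346% to 0.214% of the counts of a library. The interval table was taken as counts per LINE copy when the tests were set, but it holds all repeat classes and intervals without an element name, with 308 element names, 254 of which join several, so sums were made per element name. Of its intervals 5872 had no count, the longest spanned 148 bp, and 34.8% lay outside the gene spans of the RefSeq annotation of GRCm38.p6. Exons within those spans were not known here. Chromosomes and positions are as deposited. Among 192 pairs of libraries of 1 group 0 were identical (smallest chi-square per degree of freedom 9.14).

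Groups followed the labels, 1 per fraction and time. The labels do not say that libraries come from separate animals, so each p-value measures the spread between libraries. Each fraction was fitted as 1 model of 7 groups in edgeR 4.0.16 under R 4.3.3, with TMM scaling, filterByExpr and robust quasi-likelihood F-tests, and each time was compared with naive. IP against naive Input, and the F-test of the 6 differences between the IP and Input responses, came from 1 fit of 14 groups. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and calls use 0.05. Standard errors of log2 changes were computed from the F statistics. Unadjusted p-values of the 6 comparisons of log2 interval reads per gene read came from exact 2-sided permutation tests, adjusted over the 6 times. CPM values use the TMM-scaled library size of the gene table, for intervals too.

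The 29 gene lists, written from general knowledge, held 669 members, of which 652 matched the table. They cover regeneration-associated, immediate early, sensory ion channel, sensory subtype, pan-neuronal, satellite glia, Schwann and myelin, macrophage, neutrophil and lymphocyte, endothelial, fibroblast, mural, erythrocyte, proliferation, cholesterol synthesis, integrated stress, ER chaperone, interferon response, cytokine and chemokine, circadian clock, glucocorticoid response, tubulin and neurofilament, neuropeptide, synaptic vesicle, axon guidance and adhesion, ribosomal protein, sex-linked, repeat-silencing and mitochondrially encoded genes. No mitochondrially encoded member matched a symbol of the table, so that list was not analysed here. Lists overlap: 12 of 20 neuropeptides, 10 of 20 pan-neuronal and 17 of 47 regeneration-associated members stand in another list. Naive Input also expressed 21 of 21 macrophage, 12 of 12 fibroblast, 8 of 14 neutrophil and lymphocyte and 18 of 18 myelin genes above a mean of 1 CPM. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01, and adjustment over all lists and times of a fraction. A correlation estimated per list was the stricter alternative.

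The genes named in the text follow a rule. For each time in IP these were the 6 rising and 6 falling genes of largest fold change that passed, reached a mean of 5 CPM in the higher group and had every library of that time on 1 side of the naive mean. The numbers were 4 and 4 in Input and 8 and 8 for IP against Input, with up to 4 passing members of smallest adjusted p from each list, and Rpl10a. For intervals and element sums these were the 3 rising and 3 falling of largest change with at least 1 CPM. A gene without a count in 1 group is given as at least the fold over a floor of 3 counts summed over that group. Genes with 1 to 3 counts are given as a ratio with a 95% interval for the counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Some genes that this rule named are not reported here. Paralogs, overlapping genes and antisense partners could share reads here. The tests, alternatives, lists and naming rule were set before the data were examined, except where the text says that they were chosen later.

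Alternatives were DESeq2-type size factors (RLE), no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma voom with quality weights, a fit of the 2 groups alone, a replicate block, a covariate of glial markers, leaving out each library in turn, and for intervals other scalings, a mean of 10 counts and intervals outside genes only. Covariates of rRNA share and of sex (log2 Ddx3y minus Xist), leaving out Rn45s and Lars2, leaving out libraries of mostly rRNA, scaling by intervals without an element name and, for the difference between the responses, DESeq2's likelihood ratio test were chosen after seeing the data. Naive replicate 1 had a log2 CPM of Xist and Ddx3y of -2.66 and 4.97 in Input and 8.05 and 1.05 in IP, and replicate 2 had 4.79 and -0.89 in Input and -0.70 and 5.31 in IP, so equal numbers need not be 1 animal.

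Each test of counts was checked on counts simulated from the real means and library sizes with a seeded set of changed genes. Genes varied independently there, so structure of the samples such as rRNA share or sex is not in these numbers. The permutation test was checked on random normal values instead, where 4% of 200 data sets without a shift had a p under 0.05. Of 98 genes changed 4-fold among 18121 tested, 48.0% (IP at 1 h) to 71.4% (IP at 7 d) were recovered in IP, and of 100 among 16012 85.0% (7 d) to 90.0% (72 h) in Input. Of genes changed 2-fold 17.2% were recovered in IP at 1 h and 66.0% in Input at 1 h, so small changes were missed more often in IP. False calls numbered 72 in IP at 7 d and 77 of 19253 genes for the difference between the responses. For IP intervals 60.0% of 4-fold changes were recovered with 356 false calls among 59908, and for list tests 1 of 1 changed list with 2 other calls of 168. Other splits of the real libraries gave far more list calls than that, a median of 33 in IP. For genes in IP at 12 h such splits gave a median of 0 but up to 3426 calls, against 9 false calls in the simulation.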

Results

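RNA was sequenced from the lumbar dorsal root ganglia that hold the cell bodies of sciatic sensory neurons, taken from uninjured (naive) BR145-GFP mice or after crush of both sciatic nerves. Each time had whole-tissue RNA (Input) and RNA pulled down with an antibody to GFP (IP). The 40 Input libraries were 7 naive, 5 at 1 h, 6 at 12 h, 5 at 24 h, 6 at 48 h, 7 at 72 h and 4 at 7 d, and the 39 IP libraries had the same numbers except 4 at 24 h. Gene counts per library ran from 8737964 to 22221882 in Input and from 3614942 to 16721527 in IP. Rn45s, the ribosomal RNA precursor, and Lars2, whose transcript holds an rRNA-like stretch, took 1.64% to 25.5% of these counts in Input and 1.37% to 75.1% in IP. That share was 27.3 ± 11.7% in naive IP (SD, n = 7), 41.0 ± 31.3% at 1 h (n = 5) and 4.14 ± 2.99% at 7 d (n = 4). All 12 h libraries had more counts on Y-linked Ddx3y than on Xist, all 48 h libraries had the reverse, and every other group held both kinds. Some libraries carried both markers, such as naive IP replicate 6 with a log2 CPM of 7.31 for Xist and 4.72 for Ddx3y, so these kinds need not be sexes. Xist was also higher in naive IP than in naive Input (log2 difference 3.15 ± 0.88), so the kinds are not alike in IP and Input. Changes are log2 values with their standard errors, taken against the naive group of the same fraction unless stated.

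**Figure D1:**
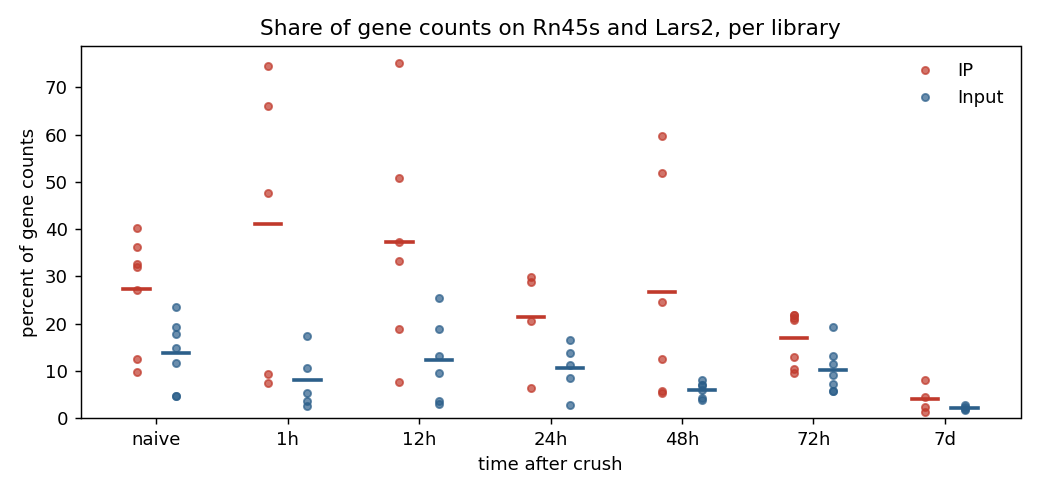
Percent of gene counts on Rn45s and Lars2 in each library (points), with the mean of each group (lines), by time after the crush and fraction. The IP means were 27.3% in naive libraries and 4.14% at 7 d, and in 6 of 39 IP libraries these genes took most of the counts.

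The naive IP and Input libraries show how pulled-down RNA differed from whole-tissue RNA. Ribosomal protein mRNAs were lower in IP, as were general neuronal mRNAs, while genes of axon guidance and adhesion were higher. Of the ribosomal proteins 2 of 79 were higher, 56 were lower and 21 did not pass, and 2 were higher and 61 were lower adjusted over the list alone (camera adjusted p = 2.8e-12, adjusted p = 0.72 with an estimated correlation). Rpl29 was at -1.42 ± 0.17. Rpl10a, the ribosomal protein that carries GFP in the usual form of this mouse system, was at -0.70 ± 0.26, with 8.61 ± 1.65 CPM in IP against 14.1 ± 2.82 in Input (SD, n = 7 each). Of the axon guidance and adhesion genes 20 of 28 were higher, 1 was lower and 7 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 8.7e-04, adjusted p = 0.72 with an estimated correlation). The netrin receptor Dcc was at 3.14 ± 0.56 and the adhesion molecule Chl1 at 0.89 ± 0.18. Of the pan-neuronal genes 2 of 20 were higher, 12 were lower and 6 did not pass, and 2 were higher and 13 were lower adjusted over the list alone (camera adjusted p = 0.0040, adjusted p = 0.77 with an estimated correlation). The ubiquitin hydrolase Uchl1 was at -1.06 ± 0.16 and the tubulin regulator Stmn2 at -1.02 ± 0.16. Of the tubulin and neurofilament genes 2 of 22 were higher, 12 were lower and 8 did not pass, and 2 were higher and 14 were lower adjusted over the list alone (camera adjusted p = 0.0040, adjusted p = 0.77 with an estimated correlation). Of the neuropeptides 7 of 20 were lower and 13 did not pass, and 6 were lower adjusted over the list alone (camera adjusted p = 0.047, adjusted p = 0.77 with an estimated correlation). Ion channels of sensory neurons went both ways, 12 of 39 were higher, 9 were lower and 18 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.71). The touch channel Piezo2 was at 1.28 ± 0.17 and the nociceptor sodium channel Scn10a at 0.92 ± 0.16. Of the myelin genes 8 of 18 were higher, 1 was lower and 9 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.12). Lead genes were the myelin scaffold genes Prx (1.57 ± 0.18) and Drp2 (1.78 ± 0.21), and Mbp, a main myelin protein, was higher too (1.21 ± 0.24). Fabp7, a marker of satellite glia, was lower (-1.67 ± 0.23), and the B cell gene Ms4a1 was higher in IP (4.30 ± 0.73). Skint5, a keratinocyte gene, was 113-fold higher, and the pheromone receptor Vmn1r13, at 2 counts over the Input libraries, had a ratio of 299 (95% counting interval 82.2 to 2480.5). Nuclear Malat1 (3.41 ± 0.28) and 144 of 1102 olfactory receptor genes (260 with enough counts to be tested) were higher too, so a higher level in IP need not come from cells with GFP. In all 9170 of 19584 genes differed, 5403 higher and 3767 lower in IP. DESeq2-type size factors moved the median of all genes by 0.12 and gave 6096 higher and 3226 lower.

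The IP fraction at 1 h gives the first change in pulled-down RNA after the crush. With an estimated correlation camera called 4 lists, ion channels as rising and macrophage, fibroblast and ribosomal protein genes as falling, while most members of each did not pass alone. Of the ion channels 4 of 39 rose and 35 did not pass, and 11 rose adjusted over the list alone (camera adjusted p = 4.0e-11, adjusted p = 0.015 with an estimated correlation). The sodium channel Scn9a rose by 0.71 ± 0.16 and Scn10a by 0.93 ± 0.21. The light neurofilament Nefl rose from 2668 ± 548 CPM in the naive group (SD, n = 7) to 6124 ± 2479 (n = 5), and Nefm rose by 1.36 ± 0.37. Among the tubulin and neurofilament genes 4 of 22 rose and 18 did not pass, and 8 rose adjusted over the list alone (camera adjusted p = 2.2e-04, adjusted p = 0.38 with an estimated correlation). Subtype genes rose at the neurotrophin receptor Ntrk3 (0.96 ± 0.20) and the nociceptor receptor Mrgprd (1.51 ± 0.37). Of the subtype genes 4 of 34 rose and 30 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.40 with an estimated correlation). Among immediate early genes 5 of 28 fell and 23 did not pass, and 1 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.26 with an estimated correlation). Btg2 was at -2.30 ± 0.38, the mRNA-decay factor Zfp36 at -2.63 ± 0.49 and Junb at -1.84 ± 0.38. Of the macrophage genes 9 of 21 fell and 12 did not pass, and 19 fell adjusted over the list alone (camera adjusted p = 4.0e-15, adjusted p = 0.0097 with an estimated correlation). The antigen-presenting gene H2-Aa was at -1.95 ± 0.32 and Tyrobp at -2.91 ± 0.55. Of the fibroblast genes 4 of 12 fell and 8 did not pass, and 10 fell adjusted over the list alone (camera adjusted p = 2.4e-09, adjusted p = 0.012 with an estimated correlation). The matrix genes Lum (-2.34 ± 0.35) and Dcn (-1.40 ± 0.21) were lower. Of the neutrophil and lymphocyte genes 4 of 14 fell and 10 did not pass, and 6 fell adjusted over the list alone (camera adjusted p = 8.1e-06, adjusted p = 0.11 with an estimated correlation). The neutrophil genes S100a9 (-4.22 ± 0.95) and Mpo (-4.21 ± 1.15) fell. Of the myelin genes 2 of 18 fell and 16 did not pass, and 7 fell adjusted over the list alone (camera adjusted p = 1.7e-04, adjusted p = 0.27 with an estimated correlation). Among the ribosomal proteins 11 of 79 fell and 68 did not pass, and 31 fell adjusted over the list alone (camera adjusted p = 2.1e-16, adjusted p = 0.042 with an estimated correlation). Rps14 was at -1.18 ± 0.21. In all 293 of 18656 genes changed, 124 rising and 169 falling, by edgeR's quasi-likelihood test. Without the IP libraries in which Rn45s and Lars2 took most counts 94 genes passed, with a glial marker covariate 100, and by DESeq2 661.

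At 12 h the IP fraction held the first rise of injury genes. Atf3, a transcription factor switched on in injured neurons, rose from 7.08 ± 5.80 CPM in the naive group (SD, n = 7) to 100.4 ± 44.8 (n = 6), a log2 of 3.92 ± 0.33 (adjusted p = 5.2e-12). The transcription factors Sox11 (2.60 ± 0.22) and Jun (1.59 ± 0.18), the growth-arrest gene Gadd45a (2.58 ± 0.23), the cytokine-signal inhibitor Socs3 (3.07 ± 0.51), the protease inhibitor Timp1 (2.59 ± 0.52) and the neurotrophin Bdnf (1.82 ± 0.21) rose as well. Of the regeneration-associated genes 10 of 44 rose and 34 did not pass, and 14 rose and 3 fell adjusted over the list alone (camera adjusted p = 7.5e-09, adjusted p = 0.021 with an estimated correlation). Myelin genes were lower, 9 of 18 fell and 9 did not pass, and 13 fell adjusted over the list alone (camera adjusted p = 3.6e-16, adjusted p = 0.012 with an estimated correlation). Pmp22 was at -1.06 ± 0.18 and Fabp7 at -1.52 ± 0.22. Of the macrophage genes 11 of 21 fell and 10 did not pass, and 14 fell adjusted over the list alone (camera adjusted p = 1.1e-14, adjusted p = 0.010 with an estimated correlation). Of the fibroblast genes 7 of 12 fell and 5 did not pass, and 8 fell adjusted over the list alone (camera adjusted p = 5.3e-14, adjusted p = 0.0019 with an estimated correlation). Lum was at -3.02 ± 0.33 and the collagen gene Col1a2 at -1.37 ± 0.22. Of the ribosomal proteins 11 of 79 fell and 68 did not pass, and 31 fell adjusted over the list alone (camera adjusted p = 3.6e-16, adjusted p = 0.044 with an estimated correlation). Rpl32 was at -1.12 ± 0.16. Nr4a1, an immediate early gene, was lower (-2.24 ± 0.41), and Xist (-9.75 ± 1.69) and its antisense partner Tsix (-7.61 ± 1.41) fell in this group, where every library had more Ddx3y than Xist, their reads not separable without strand. In all 423 of 18656 genes changed, 219 rising and 204 falling. A sex score covariate gave 40, a glial marker covariate 33, and the fit without libraries of mostly rRNA 216. Leaving out 1 library gave 213 to 704, and 6 of 100 splits of these libraries, the real one included, gave as many.

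At 24 h in IP the regeneration-associated genes rose broadly: 32 of 44 rose and 12 did not pass, and 36 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.7e-48, adjusted p = 1.0e-07 with an estimated correlation). Gadd45a rose from 30.7 ± 7.39 CPM in the naive group (SD, n = 7) to 497 ± 90.7 (n = 4), a log2 of 4.01 ± 0.25 (adjusted p = 8.1e-17). Atf3 was up by 5.07 ± 0.35, Sox11 by 3.27 ± 0.23, Socs3 by 4.47 ± 0.51, the cornified-envelope protein gene Sprr1a by 4.55 ± 0.69, the laminin receptor subunit Itga7 by 2.00 ± 0.24 and the microtubule regulator Stmn4 by 2.27 ± 0.26. Of the neuropeptides 7 of 19 rose and 12 did not pass, and 8 rose adjusted over the list alone (camera adjusted p = 5.7e-06, adjusted p = 0.087 with an estimated correlation). Npy was at 4.07 ± 0.56 and galanin (Gal) at 2.83 ± 0.41, and the macrophage growth factor Csf1 rose by 1.92 ± 0.33. Lce1g, a late-envelope gene with 1 naive count, had a ratio of 369.9 (95% counting interval 65.8 to 14668). Of the tubulin and neurofilament genes 2 of 22 rose and 20 did not pass, and 14 rose adjusted over the list alone (camera adjusted p = 6.1e-10, adjusted p = 0.11 with an estimated correlation). Of the fibroblast genes 7 of 12 fell and 5 did not pass, and 12 fell adjusted over the list alone (camera adjusted p = 3.6e-16, adjusted p = 7.8e-04 with an estimated correlation). Col1a2 was at -1.82 ± 0.26. Of the macrophage genes 6 of 21 fell and 15 did not pass, and 15 fell adjusted over the list alone (camera adjusted p = 2.3e-09, adjusted p = 0.045 with an estimated correlation). Tyrobp was at -3.01 ± 0.56. Of the myelin genes 4 of 18 fell and 14 did not pass, and 12 fell adjusted over the list alone (camera adjusted p = 9.3e-07, adjusted p = 0.15 with an estimated correlation). Gm10248, with no count, was at least 96.6-fold lower. In all 516 of 18656 genes changed, 354 rising and 162 falling. A glial marker covariate gave 198 genes, limma voom 165, and leaving out replicate 2 of the 24 h group 231.

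At 48 h in IP most regeneration-associated genes were higher than in naive IP, and more neuropeptides rose than fell. Sprr1a rose from 1.30 ± 2.62 CPM in the naive group (SD, n = 7) to 169 ± 82.3 (n = 6), a log2 of 7.31 ± 0.67 (adjusted p = 2.6e-11). Among the regeneration-associated genes 34 of 44 rose and 10 did not pass, and 36 rose adjusted over the list alone (camera adjusted p = 4.9e-86, adjusted p = 1.5e-10 with an estimated correlation). Atf3 was at 5.28 ± 0.34, Sox11 at 3.75 ± 0.22, Stmn4 at 3.07 ± 0.25 and the growth-cone protein Gap43 at 1.77 ± 0.19. Of the neuropeptides 7 of 19 rose, 2 fell and 10 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 1.3e-08, adjusted p = 0.032 with an estimated correlation). Npy rose by 5.84 ± 0.53, Gal by 5.19 ± 0.42 and PACAP (Adcyap1) by 2.19 ± 0.21. Corticotropin-releasing hormone (Crh, 3 naive counts) had a ratio of 184 (95% counting interval 62.8 to 897), and substance P (Tac1) fell (-0.84 ± 0.16). The growth factor gene Fgf3 rose by 5.47 ± 0.92, Csf1 by 3.19 ± 0.31, the semaphorin Sema6a by 2.95 ± 0.25 and the GDNF receptor Gfra1 by 1.57 ± 0.19. Among the tubulin and neurofilament genes 7 of 22 rose and 15 did not pass, and 8 rose adjusted over the list alone (camera adjusted p = 7.8e-10, adjusted p = 0.11 with an estimated correlation). Tubb6 was at 2.92 ± 0.28. Among the ion channels 1 of 39 rose, 5 fell and 33 did not pass, and 1 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.030, adjusted p = 0.43 with an estimated correlation). The acid sensor Asic3 was at -1.06 ± 0.24. Of the axon guidance and adhesion genes 5 of 28 rose and 23 did not pass, and 5 rose and 1 fell adjusted over the list alone. Camera gave this list as rising (camera adjusted p = 0.035, adjusted p = 0.38 with an estimated correlation), as did its mean, but its median was -0.11 and turned positive without the libraries of mostly rRNA. Among fibroblast genes 4 of 12 fell and 8 did not pass, and 6 fell adjusted over the list alone (camera adjusted p = 2.8e-06, adjusted p = 0.049 with an estimated correlation). Dcn was at -1.43 ± 0.20. Among macrophage genes 6 of 21 fell and 15 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 2.0e-04, adjusted p = 0.24 with an estimated correlation). H2-Aa was at -1.77 ± 0.29. In all 600 of 18656 genes changed, 408 rising and 192 falling.

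At 72 h in IP, of the regeneration-associated genes 34 of 44 rose and 10 did not pass, and 36 rose adjusted over the list alone (camera adjusted p = 4.1e-91, adjusted p = 1.4e-10 with an estimated correlation). Sprr1a rose from 1.30 ± 2.62 CPM in the naive group (SD, n = 7) to 321 ± 73.2 (n = 7), a log2 of 8.23 ± 0.68 (adjusted p = 8.8e-13). The endopeptidase gene Ecel1 rose by 5.43 ± 0.63, the cholecystokinin receptor Cckbr by 5.67 ± 0.57 and Gap43 by 2.12 ± 0.19. Of the neuropeptides 7 of 19 rose, 2 fell and 10 did not pass, and 8 rose and 5 fell adjusted over the list alone (camera adjusted p = 1.9e-08, adjusted p = 0.034 with an estimated correlation). Npy was at 6.66 ± 0.53, Gal at 5.79 ± 0.43, Nts at 4.02 ± 0.30 and Tac1 at -0.93 ± 0.16. Among genes of the integrated stress response 4 of 22 rose and 18 did not pass, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.4e-04, adjusted p = 0.0082 with an estimated correlation). Asparagine synthetase (Asns) was at 0.95 ± 0.26 and the folate enzyme Mthfd2 at 0.93 ± 0.20. Among ion channels 1 of 39 rose, 8 fell and 30 did not pass, and 2 rose and 18 fell adjusted over the list alone (camera adjusted p = 1.4e-08, adjusted p = 0.041 with an estimated correlation). The serotonin-gated channel Htr3a was at -1.90 ± 0.32 and the sodium channel Scn1a at -1.04 ± 0.18. Of the subtype genes 3 of 34 rose, 5 fell and 26 did not pass, and 3 rose and 11 fell adjusted over the list alone (camera adjusted p = 6.3e-04, adjusted p = 0.24 with an estimated correlation). The synaptic protein gene Snap25 was at -0.96 ± 0.21. Of the tubulin and neurofilament genes 7 of 22 rose, 1 fell and 14 did not pass, and 9 rose and 3 fell adjusted over the list alone (camera adjusted p = 8.9e-07, adjusted p = 0.23 with an estimated correlation). The fat cell genes Cfd (-3.82 ± 0.71), Fabp4 (-3.49 ± 0.93) and Cidec (-3.43 ± 0.69) were lower than in naive IP. In all 650 of 18656 genes changed, 401 rising and 249 falling. Limma voom gave 1089 and a fit of the 2 groups alone 1017.

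At 7 d the IP group had the lowest mean rRNA share of the IP groups, and 5289 of 18656 genes changed, 2440 rising and 2849 falling. Sprr1a rose from 1.30 ± 2.62 CPM in the naive group (SD, n = 7) to 893 ± 171 (n = 4), a log2 of 9.71 ± 0.72 (adjusted p = 2.5e-14). Npy rose by 8.06 ± 0.56, Ecel1 by 7.23 ± 0.67, Cckbr by 7.43 ± 0.57, Gal by 6.13 ± 0.45, Csf1 by 4.30 ± 0.33 and Gap43 by 2.82 ± 0.21, and Crh had a ratio of 353 (95% counting interval 121 to 1713). Of the regeneration-associated genes 38 of 44 rose, 1 fell and 5 did not pass, and 39 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.7e-45, adjusted p = 1.7e-07 with an estimated correlation). Stress response genes rose, 11 of 22 rose, 1 fell and 10 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 4.9e-04, adjusted p = 0.0082 with an estimated correlation). Asns was at 2.15 ± 0.29 and the glutathione-degrading enzyme Chac1 at 3.13 ± 0.54. Of the cholesterol synthesis genes 12 of 22 rose and 10 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 2.9e-05, adjusted p = 0.23 with an estimated correlation). Idi1 was at 2.16 ± 0.40. Of the pan-neuronal genes 9 of 20 rose, 1 fell and 10 did not pass, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.2e-04, adjusted p = 0.38 with an estimated correlation). Among the tubulin and neurofilament genes 11 of 22 rose, 2 fell and 9 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 1.1e-05, adjusted p = 0.27 with an estimated correlation). Tubb4a was at 2.90 ± 0.33. The ATP-gated channel P2rx3 rose (1.57 ± 0.19) and the cold channel Trpm8 fell (-2.31 ± 0.44). Of the ion channels 8 of 39 rose, 9 fell and 22 did not pass, and 9 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.70). Among the ribosomal proteins 1 of 79 rose, 39 fell and 39 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 1.4e-07, adjusted p = 0.23 with an estimated correlation). Rps21 was at -2.27 ± 0.31. Of the clock genes 3 of 18 rose, 7 fell and 8 did not pass, and 3 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.16 with an estimated correlation). Per3 was at -1.73 ± 0.26. Among repeat-silencing genes the corepressor Trim28 rose (1.15 ± 0.24), and the maintenance DNA methyltransferase Dnmt1 (-1.34 ± 0.31) and the chromatin remodeller Atrx (-1.39 ± 0.33) fell, Atrx to 0.0250 with the rRNA share as a covariate (list 2 rose of 24 and 8 fell, camera adjusted p = 0.19). Adam34, a testis protease gene without a 7 d count, was at least 192-fold lower. With that covariate 1756 genes passed, 989 rising and 767 falling, and the median of all genes moved by 0.20.

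**Figure D2:**
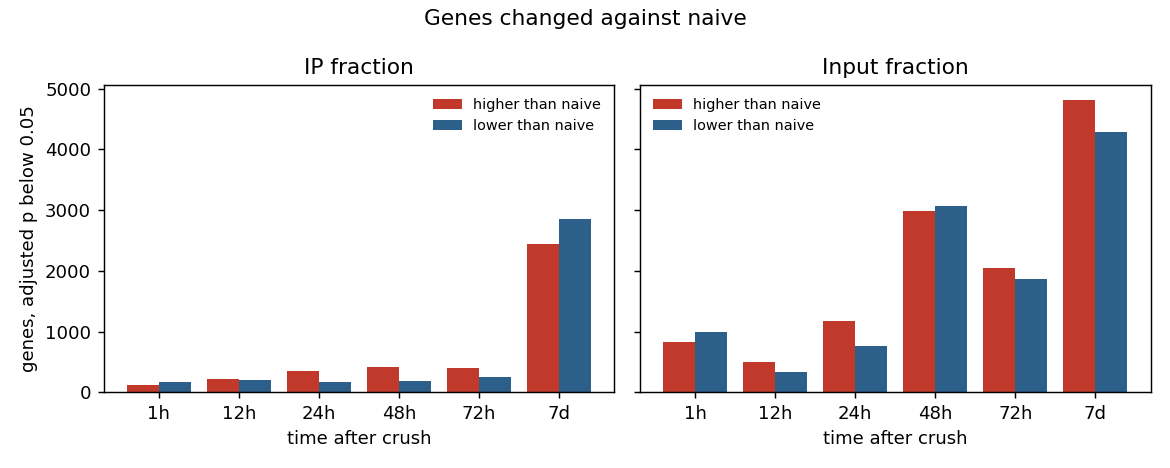
Number of genes higher (red bars) or lower (blue bars) than naive at an adjusted p under 0.05, by time after the crush, in IP (left) and Input (right). In IP 293 genes changed at 1 h and 5289 at 7 d, and in Input 1819 at 1 h and 9106 at 7 d.

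The Input fraction gives the response of whole ganglia. Reads on satellite DNA split its groups: in CPM each library at 24 h, 48 h and 7 d had 32.1 to 43.9, and each naive, 1 h, 12 h and 72 h library 102 or more, so for genes that changed at 24 h, 48 h or 7 d alone a batch and the time cannot be told apart. The labels name no batch, and most regeneration-associated genes rose at 72 h too. The same limit may hold for IP, whose satellite reads were too many and too variable to show such a split. At 1 h, ribosomal protein and fibroblast genes were lower than in naive Input. Of the ribosomal proteins 56 of 79 fell and 23 did not pass, and 67 fell adjusted over the list alone (camera adjusted p = 2.9e-29, adjusted p = 0.26 with an estimated correlation). Rpl37 was at -1.04 ± 0.24. Of the fibroblast genes 9 of 12 fell and 3 did not pass, and 12 fell adjusted over the list alone (camera adjusted p = 1.0e-11, adjusted p = 0.046 with an estimated correlation). Lum was at -1.49 ± 0.21 and Col1a1 at -1.48 ± 0.27. The fat cell genes Cfd (-3.99 ± 0.90) and Fabp4 (-3.53 ± 0.82), the adipokine Retn (-4.17 ± 0.77) and the neutrophil peptide gene Camp (-3.02 ± 0.79) fell. Of the macrophage genes 6 of 21 fell and 15 did not pass, and 8 fell adjusted over the list alone (camera adjusted p = 9.8e-06, adjusted p = 0.45 with an estimated correlation). Of the cytokine and chemokine genes 1 of 20 rose, 6 fell and 13 did not pass, and 1 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.0095, adjusted p = 0.39 with an estimated correlation). Ccl7 was at -1.61 ± 0.30. Among the ion channels 5 of 38 rose and 33 did not pass, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.43 with an estimated correlation). The capsaicin receptor Trpv1 was at 1.05 ± 0.32. Sgk1, a hormone-responsive kinase gene, rose from 23.3 ± 6.01 CPM in the naive group (SD, n = 7) to 43.9 ± 8.32 (n = 5). The protocadherin Pcdhac1 rose by 1.38 ± 0.33 and Bdnf by 0.51 ± 0.14. In all 1819 of 16217 genes changed, 834 rising and 985 falling. The count rested on single libraries: without replicate 4 of the 1 h group it was 193, without naive replicate 3 it was 3460, and a fit of the 2 groups alone gave 38.

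At 12 h in Input, Atf3 rose from 13.9 ± 3.91 CPM in the naive group (SD, n = 7) to 324 ± 77.8 (n = 6), a log2 of 4.57 ± 0.16 (adjusted p = 2.7e-25). Among the regeneration-associated genes 22 of 46 rose, 1 fell and 23 did not pass, and 25 rose and 4 fell adjusted over the list alone (camera adjusted p = 9.4e-24, adjusted p = 1.3e-04 with an estimated correlation). Gadd45a rose by 2.36 ± 0.14, Sox11 by 2.59 ± 0.19, Socs3 by 2.75 ± 0.29, Bdnf by 1.63 ± 0.13, the cytokine Il6 by 3.10 ± 0.35, the metalloreductase Steap1 by 3.52 ± 0.24 and the glial filament gene Gfap by 3.01 ± 0.39. Among cholesterol synthesis genes 9 of 22 rose and 13 did not pass, and 15 rose adjusted over the list alone (camera adjusted p = 2.3e-10, adjusted p = 0.0056 with an estimated correlation). The mevalonate enzyme Mvd was at 0.66 ± 0.09 and the pathway regulator Insig1 at 0.59 ± 0.09. Of the immediate early genes 1 of 28 rose, 11 fell and 16 did not pass, and 3 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.0068, adjusted p = 0.51 with an estimated correlation). Egr3 was at -2.44 ± 0.49. Clock genes went both ways, 2 of 18 rose, 5 fell and 11 did not pass, and 4 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.23). Bhlhe41 was at 1.10 ± 0.15 and Dbp at -1.43 ± 0.15. Of the fibroblast genes 8 of 12 fell and 4 did not pass, and 11 fell adjusted over the list alone (camera adjusted p = 9.2e-15, adjusted p = 0.029 with an estimated correlation). Xist, with 2 counts over the 12 h libraries, was lower by a ratio of 696 (95% counting interval 192 to 5756). In all 824 of 16217 genes changed, 495 rising and 329 falling, and a sex score covariate gave 185. Leaving out 1 library gave 480 to 1432, and 5 of 100 splits of these libraries, the real one included, gave as many.

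At 24 h in Input, of the regeneration-associated genes 37 of 46 rose and 9 did not pass, and 39 rose adjusted over the list alone (camera adjusted p = 1.7e-61, adjusted p = 1.8e-08 with an estimated correlation). Atf3 rose from 13.9 ± 3.91 CPM in the naive group (SD, n = 7) to 618 ± 103 (n = 5), a log2 of 5.50 ± 0.17 (adjusted p = 7.7e-28). The receptor gene Gpr151 rose by 5.49 ± 0.38, Fgf3 by 5.49 ± 0.42, Lce1g by 6.21 ± 0.48, Gadd45a by 3.70 ± 0.15 and Csf1 by 1.88 ± 0.19. Of the neuropeptides 8 of 19 rose and 11 did not pass, and 9 rose adjusted over the list alone (camera adjusted p = 2.2e-09, adjusted p = 0.045 with an estimated correlation). Npy was at 4.79 ± 0.36, Gal at 2.88 ± 0.17 and Adcyap1 at 2.30 ± 0.13. Il6 (3.56 ± 0.34), Gfap (3.22 ± 0.39) and the clock-linked factor Nfil3 (1.96 ± 0.21) rose. Of the stress response genes 9 of 22 rose, 1 fell and 12 did not pass, and 11 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.074 with an estimated correlation). Fibroblast genes were lower, 10 of 12 fell and 2 did not pass, and 12 fell adjusted over the list alone (camera adjusted p = 3.9e-11, adjusted p = 0.054 with an estimated correlation). Dcn was at -1.23 ± 0.17. Among macrophage genes 8 of 21 fell and 13 did not pass, and 11 fell adjusted over the list alone (camera adjusted p = 5.5e-05, adjusted p = 0.50 with an estimated correlation). The CSF1 receptor Csf1r was at -1.50 ± 0.26. In all 1937 of 16217 genes changed, 1179 rising and 758 falling.

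At 48 h in Input, genes of regeneration rose while ion channel genes fell. Gal rose from 30.2 ± 7.98 CPM in the naive group (SD, n = 7) to 1030.3 ± 191 (n = 6), a log2 of 5.09 ± 0.18 (adjusted p = 6.4e-26), Sprr1a by 8.51 ± 0.43, Gpr151 by 7.57 ± 0.34 and Atf3 by 5.94 ± 0.17. Of the regeneration-associated genes 43 of 46 rose and 3 did not pass, and 43 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.6e-48, adjusted p = 2.0e-07 with an estimated correlation). Cckbr, with 2 naive counts, had a ratio of 583 (95% counting interval 161 to 4815). Of the ion channels 21 of 38 fell and 17 did not pass, and 1 rose and 21 fell adjusted over the list alone (camera adjusted p = 2.5e-07, adjusted p = 0.032 with an estimated correlation). The sodium channel Scn11a was at -1.62 ± 0.20 and Scn10a at -1.07 ± 0.14. Of the subtype genes 5 of 34 rose, 17 fell and 12 did not pass, and 6 rose and 18 fell adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.12 with an estimated correlation). Mrgprd was at -1.21 ± 0.16 and the artemin receptor Gfra3 at 1.43 ± 0.14. Of the proliferation genes 10 of 20 rose and 10 did not pass, and 12 rose adjusted over the list alone (camera adjusted p = 0.0095, adjusted p = 0.50 with an estimated correlation). The mitotic kinase Pbk was at 2.11 ± 0.44 and the replication factor Mcm5 at 1.29 ± 0.22. Among the ribosomal proteins 2 of 79 rose, 44 fell and 33 did not pass, and 3 rose and 47 fell adjusted over the list alone (camera adjusted p = 7.0e-07, adjusted p = 0.71 with an estimated correlation). Y-linked Ddx3y, without a count at 48 h, was at least 319-fold lower. In all 6056 of 16217 genes changed, 2984 rising and 3072 falling.

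At 72 h in Input, ion channel and subtype genes were lower and macrophage and proliferation genes higher. Among the ion channels 1 of 38 rose, 27 fell and 10 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 2.3e-12, adjusted p = 0.0034 with an estimated correlation). Kcna2 was at -1.28 ± 0.11 and Htr3a at -1.42 ± 0.19. Of the subtype genes 3 of 34 rose, 20 fell and 11 did not pass, and 6 rose and 22 fell adjusted over the list alone (camera adjusted p = 1.4e-05, adjusted p = 0.0045 with an estimated correlation). The proprioceptor factor Etv1 was at -1.15 ± 0.11 and Gfra3 at 1.54 ± 0.14. Among the regeneration-associated genes 44 of 46 rose and 2 did not pass, and 45 rose adjusted over the list alone (camera adjusted p = 1.9e-66, adjusted p = 1.3e-08 with an estimated correlation). Sprr1a rose from 1.49 ± 2.39 CPM in the naive group (SD, n = 7) to 1013 ± 221 (n = 7), a log2 of 9.56 ± 0.43 (adjusted p = 1.3e-19), and Npy rose by 7.74 ± 0.34, Gal by 5.97 ± 0.18 and Crh by 8.28 ± 0.39. Of the macrophage genes 16 of 21 rose and 5 did not pass, and 17 rose adjusted over the list alone (camera adjusted p = 6.5e-08, adjusted p = 0.36 with an estimated correlation). The complement gene C1qc was at 1.55 ± 0.18, the integrin Itgam at 1.97 ± 0.30 and the lysosomal marker Cd68 at 1.42 ± 0.22. Of the proliferation genes 12 of 20 rose and 8 did not pass, and 14 rose adjusted over the list alone (camera adjusted p = 2.2e-05, adjusted p = 0.22 with an estimated correlation). Cenpf was at 2.21 ± 0.31. Stress response genes rose, 12 of 22 rose, 1 fell and 9 did not pass, and 12 rose and 2 fell adjusted over the list alone (camera adjusted p = 6.2e-05, adjusted p = 0.032 with an estimated correlation). Chac1 was at 1.82 ± 0.21 and Mthfd2 at 1.15 ± 0.12. Of the tubulin and neurofilament genes 9 of 22 rose, 2 fell and 11 did not pass, and 10 rose and 2 fell adjusted over the list alone (camera adjusted p = 3.0e-05, adjusted p = 0.032 with an estimated correlation). In all 3915 of 16217 genes changed, 2053 rising and 1862 falling.

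At 7 d in Input, 9106 of 16217 genes changed, 4822 rising and 4284 falling. Rn45s and Lars2 took 1.64% to 2.74% of the counts of these libraries and 4.70% to 23.6% in naive Input, and with that share as a covariate 7285 genes passed. Sprr1a rose from 1.49 ± 2.39 CPM in the naive group (SD, n = 7) to 1139.8 ± 87.6 (n = 4), a log2 of 9.73 ± 0.45 (adjusted p = 1.1e-19), Ecel1 by 8.86 ± 0.34 and Chl1 by 3.06 ± 0.16. Cckbr, with 2 naive counts, had a ratio of 3089.7 (95% counting interval 855 to 25518), and the lipase gene Lipn, without a naive count, was at least 302-fold higher. Of the regeneration-associated genes 41 of 46 rose and 5 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 6.7e-27, adjusted p = 5.4e-05 with an estimated correlation). The receptor genes Gfra1 rose by 2.92 ± 0.15, Gfra3 by 2.77 ± 0.15 and Ret by 2.18 ± 0.14, as did P2rx3 (1.65 ± 0.12) and Trpv1 (2.45 ± 0.33). Of the ion channels 17 of 38 rose, 3 fell and 18 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.072). Of the cholesterol synthesis genes 19 of 22 rose, 2 fell and 1 did not pass, and 19 rose and 3 fell adjusted over the list alone (camera adjusted p = 1.7e-06, adjusted p = 0.041 with an estimated correlation). Sqle was at 1.65 ± 0.12. Of the ER chaperones 18 of 19 rose and 1 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 2.6e-08, adjusted p = 0.032 with an estimated correlation). Hspa5 was at 1.57 ± 0.14 and Calr at 1.49 ± 0.13. Of the axon guidance and adhesion genes 16 of 27 rose, 2 fell and 9 did not pass, and 17 rose and 2 fell adjusted over the list alone (camera adjusted p = 5.2e-04, adjusted p = 0.44 with an estimated correlation). Of the macrophage genes 13 of 21 rose and 8 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.0088, adjusted p = 0.71 with an estimated correlation). The glial gene Apoe rose (1.47 ± 0.13). Of the ribosomal proteins 77 of 79 fell and 2 did not pass, and 78 fell adjusted over the list alone (camera adjusted p = 4.7e-26, adjusted p = 0.30 with an estimated correlation). Rpl34 was at -2.03 ± 0.21, and the median of the list was -1.55, or -0.75 with the rRNA share as a covariate. The synaptic gene Cplx2 fell (-2.30 ± 0.20).

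**Figure D3:**
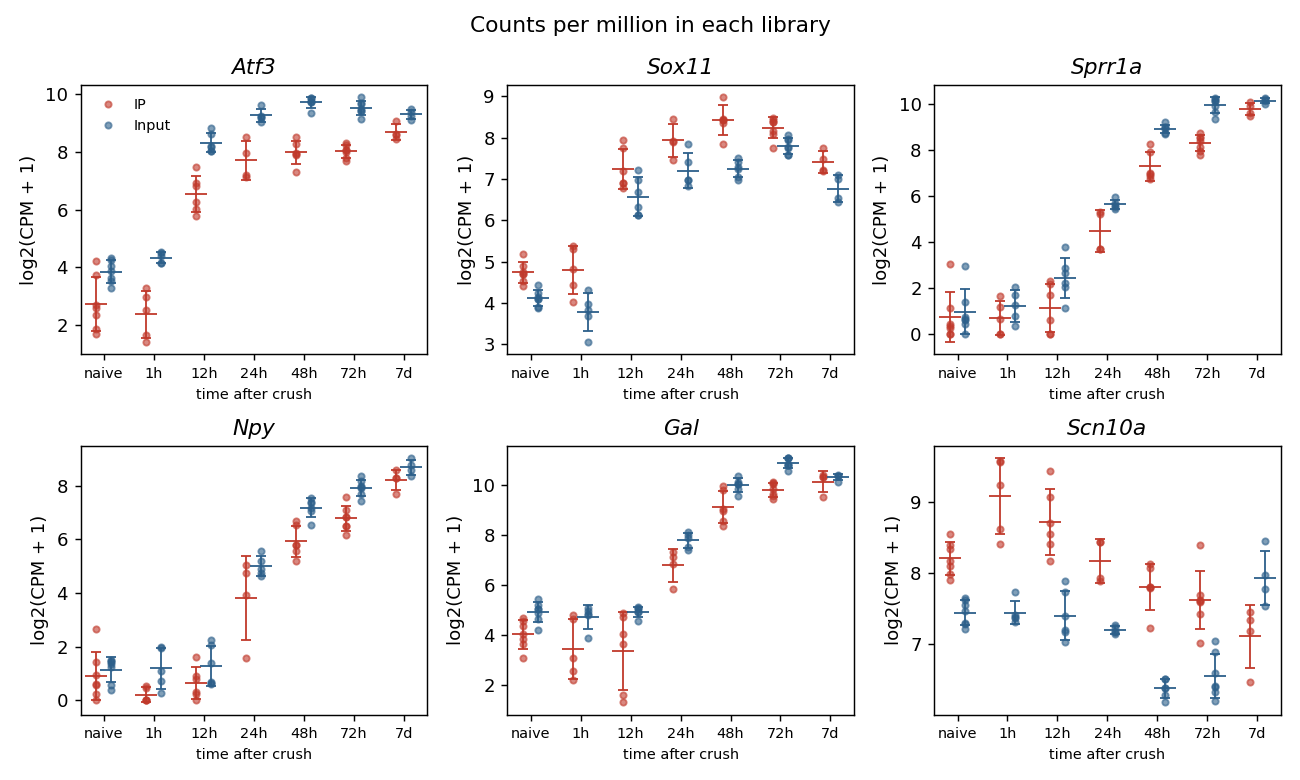
Log2 of CPM plus 1 in each library (points), with the mean and SD of each group (bars), for Atf3, Sox11, Sprr1a, Npy, Gal and Scn10a by time after the crush in IP (red) and Input (blue). Sprr1a rose by 9.71 ± 0.72 in IP and 9.73 ± 0.45 in Input at 7 d, and Scn10a was at -1.07 ± 0.14 in Input at 48 h.

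The remaining lists are given for Input at 7 d. Of the interferon response genes 14 of 26 rose and 12 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.20). Among satellite glia genes 8 of 15 rose, 2 fell and 5 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.051). Of the endothelial genes 5 of 12 rose, 2 fell and 5 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.54). Among mural genes 2 of 10 rose, 3 fell and 5 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.71). Of the erythrocyte genes 5 of 5 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.093). Among glucocorticoid response genes 2 of 16 rose, 7 fell and 7 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.23). Of the synaptic vesicle genes 12 of 24 rose, 4 fell and 8 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.50). Among repeat-silencing genes 4 of 24 rose, 9 fell and 11 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.41). Of the sex-linked genes 6 of 6 did not pass, and 6 did not pass adjusted over the list alone (camera adjusted p = 0.98). Satellite glia, endothelial, mural, glucocorticoid response, sex-linked and repeat-silencing lists had no camera call at any time in either fraction. Mitochondrially encoded genes were not analysed here.

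**Figure D4:**
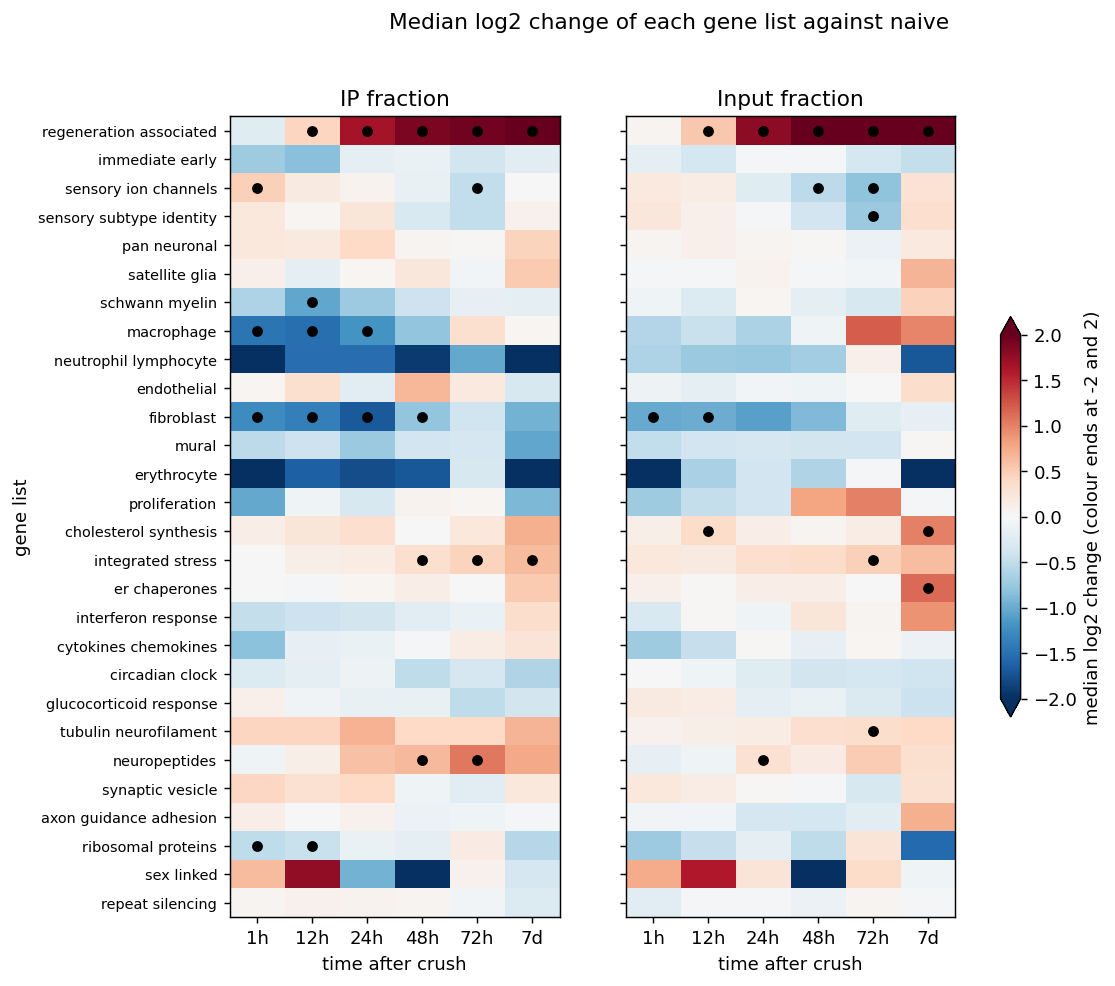
Median log2 change against naive of each gene list (colour, ending at a change of 2 either way), by time after the crush in IP and Input, with a black dot where camera with an estimated correlation called the list. The regeneration-associated list was called from 12 h to 7 d in both fractions, with a median of 0.43 at 12 h and 2.37 at 7 d in IP.

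Over the time course the IP and Input responses to the crush differed for 2342 of 19584 genes by edgeR's F-test of the 6 differences. The count was 1280 without Input replicate 1 at 7 d, 1476 without replicate 4 and 1497 under limma voom. At 7 d alone 2982 genes differed, 1740 with the more positive change in IP and 1242 with the more negative. Input at 7 d was among the groups low in satellite reads. In IP satellite reads ran from 17339.5 ± 9965 CPM at 7 d (SD, n = 4) to 56481 ± 28976 in naive libraries (n = 7). A split of the size seen in Input could not show there. A batch, in Input alone or in both fractions, and a difference of the responses at 7 d thus cannot be told apart. The 4 lists and times of smallest camera p are given here, and no list was called with an estimated correlation. Of 79 ribosomal protein genes 44 had the more positive change in IP at 7 d (59 adjusted over the list alone; camera adjusted p = 1.3e-22, adjusted p = 0.62 with an estimated correlation). The other 3 had no member that passed over all genes in edgeR. Myelin genes at 12 h had a median difference of -0.80 (IP minus Input; 10 of 18 at an unadjusted p under 0.05, 9 adjusted over the list alone; camera adjusted p = 5.7e-10, adjusted p = 0.62 with an estimated correlation). Ribosomal protein genes at 48 h had one of 0.46 (14 of 79 at an unadjusted p under 0.05; camera adjusted p = 1.9e-07, adjusted p = 0.82 with an estimated correlation), and ion channels at 48 h one of 0.32 (15 of 39 at an unadjusted p under 0.05, 11 adjusted over the list alone; camera adjusted p = 4.3e-07, adjusted p = 0.62 with an estimated correlation). The few genes that passed at single early times are named here after their values were seen. At 1 h the cytoskeletal linker Plec (difference 1.07 ± 0.21) and Znfx1 (difference 1.17 ± 0.23) had the more positive change in IP, and at 12 h Necap2 the more negative (difference -2.0 ± 0.38). At 24 h Ksr2 was more positive (difference 1.94 ± 0.41), and the potassium channel subunit Kcne3 (difference -6.04 ± 1.29), Plekhb1 (difference -1.79 ± 0.32) and the mitochondrial carrier Ucp2 (difference -2.07 ± 0.38) more negative. At 48 h the 7 genes included the kinase Camk2a (difference 1.31 ± 0.26) and the annexin Anxa1 (difference -2.90 ± 0.58). At 72 h no gene passed in edgeR, with 1083 at an unadjusted p under 0.05.

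The series title names short interspersed elements (SINEs) as RNA regulators of growth, and a second count table covers 205981 short genomic intervals, 190680 of them 25 bp long, with repeat element names. Of its counts 70.6% lay on rRNA, 13.5% on intervals without an element name and 5.53% on 2 intervals under the joint name NA,rRNA. A further 3.85% lay on 56129 intervals of B2, a rodent SINE, 1.39% on L1, a long interspersed element (LINE), 1.24% on srpRNA and 0.838% on Alu, the family name that covers rodent B1. Counts were scaled to the gene counts of each library. Over the time course 41268 of 49929 intervals changed in Input and 22979 of 66591 in IP, and of the sums per element name 153 of 172 and 135 of 213.

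B2 intervals rose at 72 h in Input. Of 18149 tested B2 intervals 10731 rose and 44 fell, with a median log2 change of 1.14. The B2 sum went from 67775 ± 19377 CPM in the naive group (SD, n = 7) to 137662 ± 30279 at 72 h (n = 7), a log2 of 1.02 ± 0.31 (adjusted p = 0.014). The rise kept its direction in every scaling and covariate tried, the sum between 1.00 and 1.20. At 24 h 2845 B2 intervals rose and 60 fell in Input, and at 48 h 2348 rose and 1547 fell. At 1 h 10050 fell and 22 rose, and the B2 sum changed by -1.21 ± 0.35 (adjusted p = 0.0094). This fall was not particular to B2: over all names 21770 of 49929 Input intervals fell at 1 h and 596 rose. Medians were -0.73 for Alu and -0.70 for L1 intervals, but 0.12 for the retroviral ERV1 intervals. At 7 d the B2 sum in Input was at -1.04 ± 0.37, which became 0.12 when scaled to the interval table itself and 0.25 with the rRNA share as a covariate. In IP 1837 of 18159 B2 intervals rose and 30 fell at 72 h, and the sum changed by 0.49 ± 0.29 (adjusted p = 0.39, n = 7 and 7).

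**Figure D5:**
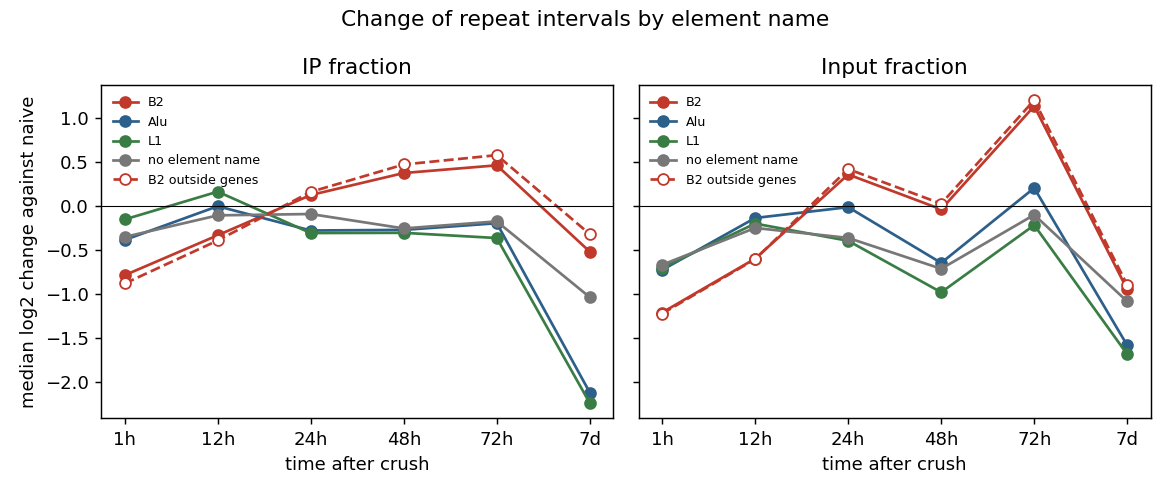
Median log2 change against naive of the tested intervals named B2, Alu and L1, of those without an element name, and of B2 intervals outside annotated genes (dashed), by time after the crush in IP (left) and Input (right). The B2 median in Input was -1.21 at 1 h, 1.14 at 72 h and -0.95 at 7 d.

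Single intervals with the largest changes were chosen by rule. In IP at 48 h a B2 interval on chromosome 13 (7749587 to 7749612, GRCm38, outside annotated genes) was at least 133-fold higher, and another within Myo1d on chromosome 11 (80757170 to 80757195) at least 126-fold higher, both without a naive count. Intervals without an element name rose within injury genes: one within Sprr1a on chromosome 3 (92483970 to 92483995) by 8.66 ± 0.83 in IP at 7 d and 9.79 ± 0.46 in Input at 72 h, and one within Cckbr on chromosome 7 (105436207 to 105436232) by at least 331-fold in Input at 7 d. A satellite interval on chromosome 9 (3000941 to 3000966) was at -7.99 ± 1.00 in Input at 48 h. Satellite reads were lower in every Input library at 24 h, 48 h and 7 d than in any naive one. For satellite falls at those times a batch and the time cannot be told apart. Among element sums the joint name B2,B4;B2 (5 intervals) rose most in IP at 72 h (4.13 ± 0.32) and B2;ERVL-MaLR (22 intervals) in Input at 72 h (3.85 ± 0.20). These are sums over few intervals, against 56129 under the name B2. The sum of srpRNA (11 intervals) fell most in IP at 7 d (-5.61 ± 1.25) and Satellite (134 intervals) in Input at 7 d (-3.93 ± 0.79).

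At 7 d most classes fell together: of 12336 Alu intervals in IP 4656 fell and 65 rose, and of 2127 L1 intervals 974 fell and 8 rose. The IP sums changed by -2.23 ± 0.57 for Alu, -2.60 ± 0.85 for L1 and -2.50 ± 1.05 for rRNA itself, and with the rRNA share as a covariate Alu was at -0.02 and L1 at 0.78. The log2 of interval reads per gene read fell by 1.96 at 7 d in IP, from 1.55 ± 0.62 (SD, n = 7) to -0.41 ± 0.80 (n = 4; exact 2-sided permutation p = 0.0030, the smallest this design allows, adjusted p = 0.018; 4 of 4 libraries below the naive mean). Of all interval counts 70.6% lay on rRNA. The measure is thus mostly one of rRNA reads and does not separate them from reads on other repeats. No other time passed in IP. In Input 7 d gave -1.72 (exact permutation p = 0.0091, adjusted p = 0.055) and 48 h -0.89 (exact permutation p = 0.028), and no time passed after adjustment. The IP call was lost without naive replicate 1, 4, 5, 6 or 7, and 3 libraries at 7 d were too few for that time to pass on its own.

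In naive ganglia 30229 of 86694 intervals differed between fractions, 27337 higher and 2892 lower in IP. Alu intervals were higher, 9895 of 18026 against 39 lower (median 2.71), as were L1 intervals, 1957 of 2841 against 19 (median 3.45). An interval could enter this test through its IP reads alone, a choice that favours intervals with reads in IP. In the fits of 1 fraction 12336 Alu and 2127 L1 intervals had enough counts in IP, against 2247 and 370 in Input. The sums differed by less, 1.30 ± 0.39 (adjusted p = 0.0034) for Alu and 0.94 ± 0.54 (adjusted p = 0.12) for L1, which did not pass. Satellite reads were far higher in IP: the sum was 56481 ± 28976 CPM in IP and 521 ± 338 in Input (SD, n = 7 each), a log2 difference of 6.89 ± 0.89 (adjusted p = 1.9e-09). B2 intervals had a median of 0.22, and the B2 sum differed by -0.15 ± 0.27 (adjusted p = 0.63). Scaled to the interval table itself the split was 17759 higher and 9234 lower, and scaled to intervals without an element name 23207 and 5627.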

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

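Among the tests in this part, those of neuronal enrichment and of a general rise of reads outside exons, and the rRNA share as a covariate, were chosen after the results were seen.

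Nuclear-retained RNAs were higher in naive IP than in naive Input, with Malat1 at 3.41 ± 0.28 and Meg3 at 2.70 ± 0.19. Neuronal RNA enriched by the pulldown is argued against as the whole cause by the pan-neuronal list, whose median was -0.48 and highest member 0.87, although camera did not call this list with an estimated correlation (adjusted p = 0.77) and 20 of 28 axon guidance and adhesion genes were higher. Genomic DNA carried into the pulldown is argued against for Malat1, which gained 1021 times as many CPM per kb as the olfactory receptor gene of largest gain among 1095, genes taken as silent in ganglia. Summed over all 1102 such genes in the table the gain was 424 CPM, so DNA stays open for genes of few counts, satellite, Alu and L1 intervals. Nuclear RNA carried into the pulldown may explain the pattern: 9 further nuclear RNAs had a median of 1.62, 6 of them higher and 1 lower. Among all genes tested 5403 of 19584 were higher.

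Some genes of fat cells, fibroblasts and neutrophils were lower after injury than in naive Input: of 12 fibroblast genes 9, 8, 10, 10, 1 and 5 fell from 1 h to 7 d in turn, and of 13 neutrophil and lymphocyte genes 4 fell at 1 h and 7 at 7 d but at most 2 at the other times. A loss of adipocyte transcripts after the crush stays open: in the mean log2 CPM of 18 adipocyte genes 5 of 7 naive libraries lay within the range of the 33 later ones, but the bound set beforehand was wrong, since such a range widens with the number of libraries, and the medians were 2.47 in naive and 1.37 in later libraries. Only 12 of the 18 genes had not been looked at before, so the gap in medians rests in part on genes already seen to be lower. Naive replicates 2 (4.47) and 3 (3.37) lay above the highest later library (2.83). Fat carried along with some naive ganglia stays a candidate source that cannot be told apart from such a loss: the 12 adipocyte genes not looked at before had medians from -1.47 to -0.75 over the 6 times (7 fell but 3 rose at 7 d), and their mean correlation over the naive libraries was 0.33, between the bounds set. Whether fibroblast and neutrophil genes share that source was not tested.

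B2 intervals rose at 72 h in Input. Transcription of the genes that hold them was tested by position: intervals outside genes rose by 1.12 times the median of those inside. This does not decide the question. How reads that match many B2 copies were assigned is not given, so reads from copies in genes may count outside them. The rRNA share of the libraries is argued against, since the B2 sum changed by 1.20 ± 0.16 with it as a covariate and by 1.02 ± 0.31 without (adjusted p = 3.1e-08 and 0.014). A general rise of reads outside exons or from DNA stays open in part: Alu intervals outside genes rose by 0.492 times the B2 median, while L1 (-0.47) and ERVK (-0.16) medians were below 0 and the Input Satellite sum changed by 0.49 ± 0.55. A response of B2 RNA to the injury stays open beside that rise and the transcription of the holding genes, and was not tested.

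The libraries of each comparison were also split in other ways into groups of the same sizes, 100 splits per result and 60 for intervals, the real split included. A bound was set on the share of splits with as many calls as the real one. For IP it was met at 1 h (293 against 930, as many in 2 splits) and 24 h (516 against 887, 3 splits). It was met as well at 48 h (600 against 211), 72 h (650 against 93) and 7 d (5289 against 3116). The first number is the count of changed genes and the second the highest of the other splits. At 1 h and 24 h in IP, and at 24 h in Input, another split gave more calls than the real one. Meeting the bound thus does not exclude chance at these times. The bound was also met for Input at 24 h (1937 against 3248, 2 splits), 48 h (6056 against 5128), 72 h (3915 against 171) and 7 d (9106 against 6505). So it was for IP against Input in naive ganglia (9170 against 4490). For the difference between the IP and Input responses (2342 against 199) the times were shuffled within each fraction separately. Such splits also remove the changes that both fractions share, so they cannot decide whether the responses differ. The bound was not met for IP at 12 h (423 against 3426, as many in 6 splits), Input at 1 h (1819 against 4917, 5 splits) and Input at 12 h (824 against 3656, 5 splits). Splits with several times the real count at these times, and at 1 h in IP, point to a structure of the samples other than the time. For calls of gene lists the bound was met in IP (70 against 77, as many in 2 splits) but not in Input (56 against 67, 13 splits). The median over the other splits was 33 list calls in IP and 44 in Input, so many list calls with the preset correlation can arise from groupings of these libraries other than the time. The bound was met too for intervals over the time course in IP (22979 against 2942) and Input (41268 against 14961), element sums in IP (135 against 27) and Input (153 against 71), and intervals in naive IP against Input (30229 against 11568).

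In 3 of 70 Dixon tests, each of 1 measure in 1 group, 1 library lay apart from the others, which chance gives in about 1 of 20 tests, and 2 of them were of the same library. IP replicate 1 at 24 h had 13296454 gene counts, against 6133430 to 6822101 in the other 3. Its log2 interval reads per gene read were 0.51, against 1.82 to 1.99. Input replicate 2 at 7 d had 37.1 CPM of satellite reads, against 32.8 to 33.5. The IP and Input responses to the crush differed for 2342 genes by edgeR's F-test of the 6 differences, a number that fell to 1280 without Input replicate 1 at 7 d and 1476 without replicate 4. Input at 7 d was among the groups low in satellite reads, so a batch at 7 d cannot be told apart from this difference there.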

How the results depend on the processing

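The rRNA and sex covariates, leaving out Rn45s and Lars2, leaving out libraries of mostly rRNA and scaling by unnamed intervals were chosen after seeing the data. Counts of called genes, intervals, sums and lists stayed within 1.5 times the reported ones under the alternatives except those named here, and the cause was not tested unless stated. In IP at 1 h (293 genes) a mean of at least 5 CPM gave 565, DESeq2 661, the rRNA share covariate 475, the sex covariate 153, Rn45s and Lars2 left out 185, the glial covariate 100 (28 rising and 72 falling) and libraries of mostly rRNA left out 94, in part by fewer libraries. In IP at 12 h (423) DESeq2 gave 751, the fit of 2 groups 281, the rRNA covariate 657, the sex covariate 40 (25 rising and 15 falling), the glial covariate 33 and libraries of mostly rRNA left out 216. In IP at 24 h (516) voom gave 165, the 2 groups 275 and the glial covariate 198 (168 rising and 30 falling). In IP at 72 h (650) voom gave 1089 and the 2 groups 1017. In IP at 7 d (5289) voom gave 2777 and the rRNA covariate 1756 (989 rising and 767 falling). At 48 h in IP the fit without libraries of mostly rRNA split 449 rising and 115 falling, against 408 rising and 192 falling. In Input at 1 h (1819) voom gave 3165, the 2 groups 38, the rRNA covariate 780 and the sex covariate 1058. In Input at 12 h (824) the 2 groups gave 225, the rRNA covariate 1374 and the sex covariate 185 (149 rising and 36 falling). The 2 groups gave 1265 in Input at 24 h (1937). IP against naive Input (9170) gave 5859 at a mean of 5 CPM, where fewer genes were tested, and the difference between the responses (2342) gave 1497 under voom. With an estimated correlation 22 of 70 list calls were made in IP and 16 of 56 in Input, and the median of axon guidance genes changed sign in IP at 24 h under RLE and at 48 h without libraries of mostly rRNA. For log2 interval reads per gene read in Input 0 times passed by the exact permutation test, and 1 without the 20 highest intervals and 1 without the 20 highest genes. Restricted to intervals outside genes, 4726 changed in IP and 9955 in Input, since fewer were tested. Element sums changed in IP (135) numbered 79 when scaled to the interval table itself, 69 with the rRNA covariate and 87 when scaled by unnamed intervals. Atrx in IP at 7 d reversed to 0.0250 with the rRNA covariate (adjusted p = 0.97 in edgeR).

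Without each library in turn the counts ran in IP from 106 to 313 at 1 h, 213 to 704 at 12 h, 231 to 505 at 24 h, 430 to 634 at 48 h, 476 to 623 at 72 h and 3775 to 5607 at 7 d, and in Input from 193 to 3460, 480 to 1432, 1543 to 2399, 5207 to 6496, 3484 to 3949 and 8255 to 9252 at these times. They ran from 8034 to 9626 for IP against naive Input, 1280 to 3211 for the difference between the responses, 17059 to 24687 and 39844 to 42183 for intervals in IP and Input, 101 to 146 and 148 to 159 for element sums, 24193 to 32219 for intervals in naive IP against Input, and 0 to 1 and 0 to 3 times for interval reads per gene read. In IP at 1 h the count was 106, 142 and 136 without 1 h replicates 1, 2 and 5, and 161, 181 and 185 without naive replicates 1, 4 and 5. In IP at 12 h it was 213, 704 and 246 without 12 h replicates 1, 3 and 4, and 268 and 277 without naive replicates 1 and 4. In IP at 24 h it was 231 and 289 without 24 h replicates 2 and 3 and 312 without naive replicate 4. In Input at 1 h it was 398, 898, 3133 and 193 without 1 h replicates 1, 2, 3 and 4, and 783, 3460, 1016, 942 and 866 without naive replicates 2, 3, 5, 6 and 7. In Input at 12 h it was 500 and 480 without 12 h replicates 1 and 2, and 1432 and 516 without naive replicates 3 and 5. Interval reads per gene read passed at 3 times in Input without naive replicate 3.

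Of 250 values of named genes 25 lost their call under voom, 4 by DESeq2, 16 with the sex covariate and 8 with the rRNA covariate, as did 14 of 122 in IP with the glial covariate and 104 of 3140 without 1 library. No library lay under 0.25 of its fraction's median total, so that alternative left nothing out. The replicate block was run since groups share replicate numbers. Equal numbers at different times did not deviate together: the median correlation was 0.00145 over 101 pairs in IP and 0.0173 over 106 in Input. For IP and Input of equal time and number it was 0.0581 over 39 pairs, against -0.0127 for unequal numbers. Of the 39 pairs 21 correlated best with their own number, among the 4 to 7 Input libraries of each time. That is more than random matching would give, so some equal numbers may share a sample, which the main fits did not model. The replicate block gave 243, 326, 354, 536, 593 and 4096 genes in IP from 1 h to 7 d, 1264, 728, 1732, 6076, 3920 and 8745 in Input, 8882 for IP against naive Input and 2158 for the difference between the responses.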

Other observations

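In Input the B2 intervals outside annotated genes changed much as those inside did, and were chosen for description after their values were seen. Of 8146 tested 7 rose and 4642 fell at 1 h, 63 and 286 at 12 h, 1459 and 14 at 24 h, 1196 and 623 at 48 h, 5191 and 8 at 72 h and 379 and 3183 at 7 d. The median log2 change was -1.22 at 1 h, 1.20 at 72 h and -0.90 at 7 d outside genes, and -1.20, 1.07 and -0.99 inside. In IP 948 of 7157 rose and 12 fell at 72 h (median 0.58). Over all intervals at 72 h in Input, 300 of 2247 Alu intervals rose and 53 fell, 23 of 370 L1 intervals rose and 25 fell, and of the retroviral ERVK intervals 33 of 646 rose and 24 fell.

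Satellite reads in Input had a CPM of 521 ± 338 in naive libraries (SD, n = 7), 1255 ± 1435 at 12 h (n = 6) and 729 ± 711 at 72 h (n = 7), against 36.7 ± 4.40 at 24 h (n = 5), 36.5 ± 3.28 at 48 h (n = 6) and 34.2 ± 1.96 at 7 d (n = 4). The IP groups showed no such split, with means from 17339.5 at 7 d to 56481 in naive libraries. Their SDs ran from 9965 at 7 d to 47229 at 48 h, so a shift of the size seen in Input could not show there. Of 1102 olfactory receptor genes 260 had enough counts to be tested between naive IP and Input, a choice that favours genes with reads in IP, and these had a median log2 difference of 4.98. The mix of sex markers in the groups was uneven: of 7 naive Input libraries 5 had more Xist than Ddx3y, against 0 of 6 at 12 h and 6 of 6 at 48 h.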
